A study of Homo sapiens with 6 samples.

How the data were processed

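RNA was measured in 6 cultures of K562, a human erythroleukaemia line that carries the BCR-ABL1 fusion and was derived from chronic myeloid leukaemia in blast crisis; the labels call the cells acute myeloid leukaemia cells. Per the labels' protocols, 3 cultures received DMSO, the solvent control, and 3 received rifamycin O at 30 µM. The time of exposure is not given in the sources used here. RNA was extracted with Trizol and libraries were made with an Illumina TruSeq RNA kit, per the labels' protocols. That kit does not mark the strand of the transcript, so reads of overlapping genes on opposite strands cannot be told apart. Groups were taken from the sample titles. Nothing in the labels says whether the replicates were separate experiments, so the p-values measure the spread between these libraries, which may be partly technical.

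The deposited table of expected counts gives an estimated number of reads for each of 63241 genes in each library, with 13.3% of the values not whole. A second deposited table gives FPKM values for the same genes and libraries, which the authors scaled to gene length and library size. The submitters' processing notes name HISAT2 2.1.0, RSEM 1.3.1, DESeq2 1.24.0 and GRCh38.p10, without stating the role of each. Both tables also hold group means made by the authors, which were not used. Lines without a gene, 25 in each table, were left out. The authors' deposited table of KEGG pathways gives, for 257 pathways, p-values, adjusted p-values and the ratio of set genes to pathway genes; those values were read as the authors' own. How its 348 genes were chosen is not given in the sources used here.

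Expected counts were rounded to whole numbers. Genes were filtered with filterByExpr at its default settings, a minimum count of 10 and a minimum total of 15, which left 15772 genes. Libraries were scaled by TMM, and rifamycin O was compared with DMSO by the two-sided quasi-likelihood F test of edgeR 4.0.16 (glmQLFit and glmQLFTest) under R 4.3.3, with the treatment as the only term. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over the genes tested. Values are given as CPM, counts scaled to the TMM-adjusted library total, as mean ± SD over 3 libraries, and fold changes are those fitted by the model. Intervals of log2 fold changes are at the 95% level and use the model's standard error and its total degrees of freedom. Library totals ran from 19334626 to 25036048 estimated reads. Gene positions and transcript GC content were taken from the GENCODE 29 annotation of GRCh38, to which 58228 gene identifiers matched. The symbols are those of the deposited table; 20601 genes had none there.

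A set of 40 gene lists, with 1127 different genes, was written before the data were examined. They cover the CRBN ligase and its reported neosubstrates, genes downstream of IKZF1 and IKZF3, stress and drug-metabolism programmes, erythroid and megakaryocyte genes, and markers of other cell types. The 38 lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1) on log2 CPM with a preset correlation of 0.01, and called at an adjusted p below 0.05 over the lists. In the lists, 35 genes belong to more than 1 list. Each list was also tested with an estimated correlation and with fry, whose directional p asks whether a list's genes move one way on balance and does not compare the list with other genes.

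The genes named in the text follow a rule set before the data were examined. The first part takes, among genes with a symbol, an adjusted p below 0.05, no overlap between the groups and a mean of at least 5 CPM in the higher group, the 12 largest rises and the 12 largest falls. The second part takes the tested members of the lists of CRBN ligase and CRBN neosubstrate genes, whatever their result. The third part takes, of every other list described, the 5 tested members with the smallest p. Genes named outside this rule are said to be so. The rule takes 223 different genes, and most of them are not reported one by one here.

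Alternatives fixed before the data were examined were RLE and upper-quartile scaling, no filter on low counts, a filter of 1 CPM in 3 libraries, limma-voom, DESeq2 1.42.0, limma on log2(FPKM + 1) and on log2(FPKM + 0.1) for genes that reach 0.5 FPKM in at least 1 library, a replicate block, leaving out each library in turn, a test against a fold of 2 (glmTreat), and other list tests. Added after the data were seen were per-library offsets for GC content and transcript length, fitted as lowess trends over a window of 0.3 of the genes and applied to the 14890 tested genes with a GC value, the same offsets without each library and with the block, the comparison without DMSO replicate 3 and rifamycin O replicate 2, and a camera test of 297 KEGG pathways taken from the annotation columns of the count table.

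The test was tried on simulated data made from the means, dispersions and library sizes of the 6 libraries, with 200 genes changed. For this comparison of 3 against 3 libraries, over 15549 genes, it recovered 66% of the genes changed 1.5-fold and 72.7% of those changed 2-fold, and 8% of its calls were false. A second simulation added GC trends as large as those of these libraries, with counts drawn anew at a lower dispersion. On it the same test without offsets recovered 57% and 75.8%, with 1.5% of its calls false. With offsets it recovered 70.2% and 82.3%, with 5.8% of its calls false. Because the dispersion differed, the first and second simulations do not isolate the effect of the trend. In simulated lists, camera called 5 of 5 lists shifted by 0.3 on the log2 scale and 1 of 30 unshifted lists. The test with an estimated correlation called 5 of 5 and 0 of 30. The simulated genes were drawn independently, whereas the estimated correlation was 0.45 for the erythroid list and 0.41 for the ATF4 list. These rates therefore do not carry over to lists of correlated genes. Libraries were compared in pairs by chi-square over genes with at least 20 reads in a pair. The value per gene was lowest for DMSO replicates 1 and 2, at 2.55, above the value near 1 that sampling alone gives. All 6 libraries were therefore kept as separate samples. DMSO replicate 3 stood at 11.6 and 11.4 from DMSO replicates 1 and 2, and at 16.8 to 27.6 from the treated libraries. DMSO replicates 1 and 2 stood at 5.58 to 9.93 from the treated libraries. Rifamycin O replicate 3 was at 5.70 and 5.58 from DMSO replicates 1 and 2, and at 6.08 and 5.32 from the other treated libraries. On this measure, without offsets, the libraries did not group cleanly by treatment.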

Results

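RNA-seq libraries of K562 erythroleukaemia cells treated with DMSO (n = 3) or with 30 µM rifamycin O (n = 3) were compared to ask how the compound changes gene expression. The study presents it as a ligand of cereblon (CRBN), the substrate receptor of a ubiquitin ligase, for the degradation of the transcription factors IKZF1 and IKZF3. Total estimated counts were 19334626, 22320279 and 25036048 in DMSO replicates 1 to 3, and 21577077, 20216959 and 23224697 in rifamycin O replicates 1 to 3. Mitochondrially encoded mRNA took between 4.02% and 4.82% of the counts. The libraries differed in their GC trend. The Spearman correlation, across genes, of a library's deviation from the gene means with GC content was 0.63 in DMSO replicate 3 and −0.463 in rifamycin O replicate 2, and lay between −0.274 and 0.101 in the other 4. Across genes, which are not independent replicates, the log2 fold change correlated with GC content at a Spearman rho of −0.355. Values after GC and length offsets, an alternative chosen after the data were seen, are therefore given beside the gene groups called.

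**Figure D1:**
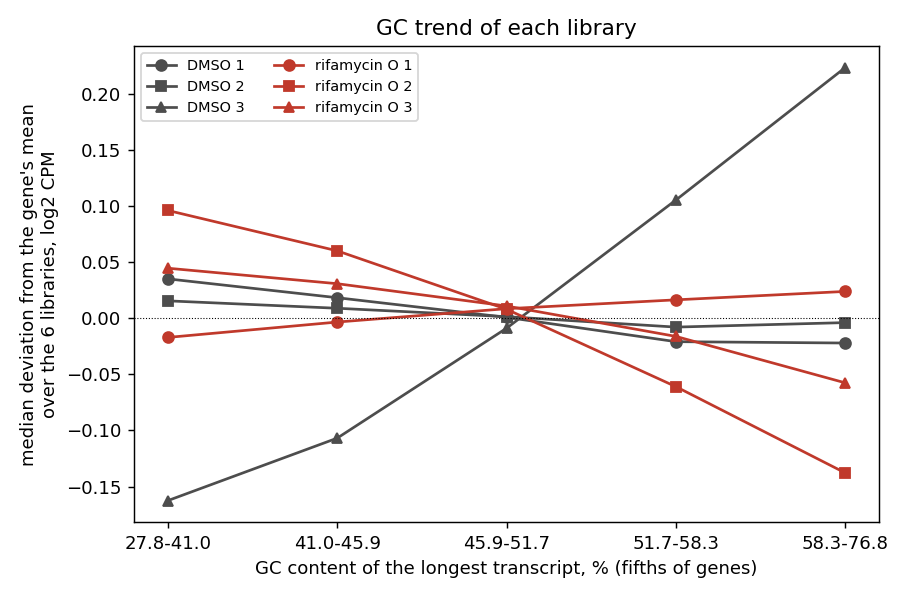
Median deviation of each library from the gene means over the 6 libraries (vertical axis, log2 CPM) in 5 equal groups of genes by GC content of the longest transcript (horizontal axis, %). DMSO replicate 3 runs from −0.16 in the group of lowest GC to 0.22 in the highest, and rifamycin O replicate 2 from 0.10 to −0.14.

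The main fit called few genes as changed between rifamycin O and DMSO, mostly by less than 2-fold, and the number called depended on the fit. The largest rises and falls given here are among called genes with a symbol and a mean of at least 5 CPM in the higher group. The largest such rises were in DYSF, a membrane repair protein (2.59-fold, 2.40 ± 0.26 to 6.26 ± 1.67 CPM, n = 3 each), and the noncoding LINC02772 (2.44-fold) and LINC00891 (2.38-fold). Next came ATF5, a stress-induced transcription factor (2.14-fold, log2 change 1.10, 95% interval 0.72 to 1.48), SLC4A1, the anion exchanger of red cells (2.09-fold), and TMEM154 (2.06-fold). They were followed by PIR (2.04-fold) and AKR1C2 (2.00-fold), both targets of the transcription factor NRF2. PHGDH (1.99-fold) and ASNS (1.97-fold), enzymes of serine and asparagine synthesis, the glycine transporter SLC6A9 (1.93-fold) and ME1, malic enzyme (1.91-fold), completed the 12. Among the largest falls were those of the interleukin-4 receptor gene IL4R (1.84-fold lower, 7.32 ± 0.97 to 3.97 ± 0.77 CPM) and ITGA2B, an integrin of platelets and megakaryocytes (1.79-fold lower). LARGE2 (1.70-fold lower), the glucose transporter SLC2A3 (1.69-fold lower, 107.6 ± 4.1 to 63.7 ± 13.9 CPM) and MS4A4A (1.69-fold lower) were also called. F2RL3, DES, DOCK6, MCAM, SPRY4 and PLCD1 were between 1.59-fold and 1.68-fold lower.

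By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 165 of 15772 genes (1.05%) were called, 118 higher and 47 lower, against 2967 genes at an unadjusted p below 0.05. The balance of directions depended on the fit. DESeq2 called 302 higher and 441 lower, and edgeR with no filter on low counts called 488 higher and 761 lower. Upper-quartile scaling called 183 higher and 117 lower, and GC and length offsets called 619 higher and 597 lower. Of the 165 genes, the 161 that have a GC value were all called again in the same direction with the offsets. Limma on log2(FPKM + 1) and on log2(FPKM + 0.1) called 14 and 16 genes, and each kept 5 of the 164 called genes tested there. In all 165 genes the 3 treated libraries lay outside the range of the 3 DMSO libraries, as did 24.7% of the genes tested, where chance gives 10%. A fitted change of at least 2-fold was reached by 16 genes, 15 higher and 1 lower, but a test against a fold of 2 (glmTreat) called 0 genes, with 24 at an unadjusted p below 0.05. The single gene at least 2-fold lower, chosen after its value was seen, was ZBED10P, a unitary pseudogene, which went from 3.55 ± 0.195 to 0.792 ± 0.341 CPM. The number of calls rested on single libraries. It was 25 without rifamycin O replicate 2, 35 without rifamycin O replicate 1, 77 without DMSO replicate 1, 255 without DMSO replicate 3 and 265 without rifamycin O replicate 3. The count at 2-fold or more was 27 without DMSO replicate 2, 8 without rifamycin O replicate 1, 6 without rifamycin O replicate 2 and 41 without rifamycin O replicate 3. Of the 24 genes taken by the rule for the largest changes, 7, 9, 19, 23 and 24 were called in those 5 fits, and all 24 kept their direction. Without each library in turn, 14.5% to 93.9% of the 165 genes were still called, and 84.8% to 97.6% when GC and length offsets were used.

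Transcripts of CRBN and of its named targets did not pass the test. CRBN, on chromosome 3 from 3144628 to 3179727 (ENSG00000113851, minus strand), was at 29.5 ± 1.5 CPM in DMSO and 32.3 ± 0.9 CPM in rifamycin O, a log2 difference of 0.13 (95% interval −0.03 to 0.30, adjusted p = 0.364, edgeR). IKZF1, on chromosome 7 from 50304068 to 50405101 (ENSG00000185811, plus strand), was at 111.4 ± 0.9 and 116.9 ± 5.1 CPM, a log2 difference of 0.07 (95% interval −0.07 to 0.20, adjusted p = 0.597, edgeR). IKZF3, on chromosome 17 from 39757715 to 39864188 (ENSG00000161405, minus strand), was at 11.6 ± 1.1 and 11.2 ± 0.7 CPM, a log2 difference of −0.05 (95% interval −0.28 to 0.19, adjusted p = 0.855, edgeR). These are RNA levels; protein was not analysed here. Of 18 tested genes of reported CRBN neosubstrates and 12 genes of the CRBN ligase, 0 were called by edgeR, with 3 of each list at an unadjusted p below 0.05, and DESeq2 also called 0. With GC and length offsets DDB1, the adaptor that joins CRBN to its cullin, was called (log2 difference −0.19, 561 ± 28 to 491 ± 14 CPM, adjusted p = 0.0322, against 0.103 without the offsets). Under the alternatives with or without offsets, CUL4B of the ligase list was called in 2 of 24 (lowest adjusted p = 0.0169), and of the neosubstrates GLUL in 4 (0.0035) and WIZ in 1 (0.0247). The neosubstrate list was not called by camera (adjusted p = 0.428), which compares it with other genes. It was called downward by fry (adjusted p = 0.0176), which asks only whether its members move one way on balance. The fry call was lost with GC and length offsets (adjusted p = 0.069 by fry). Of the neosubstrate genes, 8 had a positive and 10 a negative fitted change. Camera called neither the ligase list (0.767) nor the list of genes downstream of IKZF1 and IKZF3 (adjusted p = 0.919). Of the 12 tested members of the latter, edgeR and DESeq2 called 0, with 1 at an unadjusted p below 0.05. That gene, HES1, a transcriptional repressor, was at a log2 difference of −0.39 (95% interval −0.67 to −0.11, n = 3 each). It was called lower with GC and length offsets (adjusted p = 0.0399, against 0.128 without them) and with no filter on low counts (adjusted p = 0.0199). Other neosubstrate genes, such as GSPT1 (319.6 ± 8.0 and 321.5 ± 14.6 CPM), CSNK1A1 (219.2 ± 7.7 and 224.0 ± 9.9 CPM) and ZFP91 (121.6 ± 3.7 and 121.9 ± 3.0 CPM), differed by less than the spread between libraries.

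**Figure D2:**
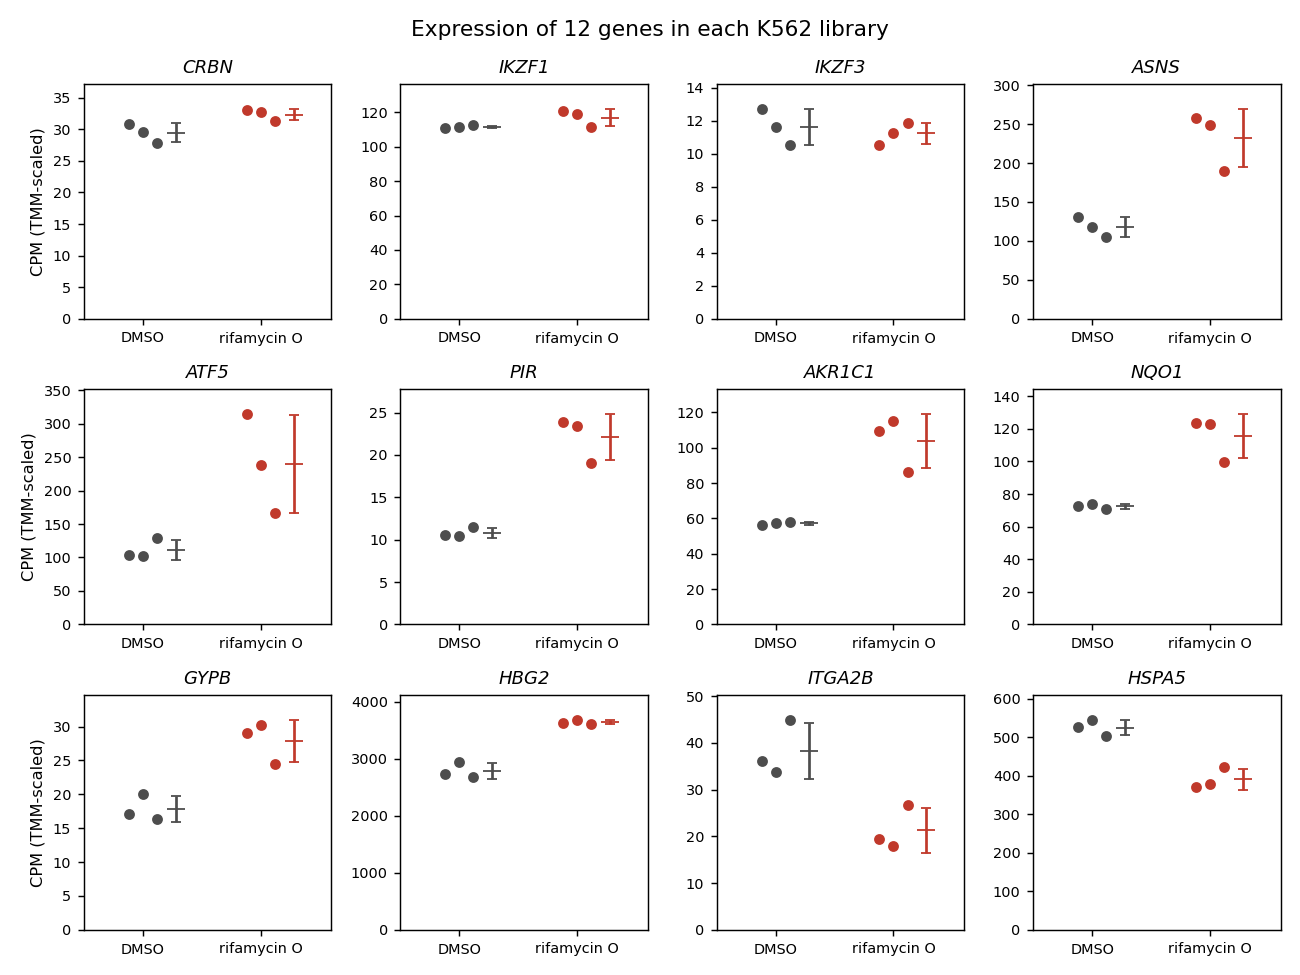
TMM-scaled CPM (vertical axes, from 0) of 12 genes in the 3 DMSO libraries (grey) and the 3 rifamycin O libraries (red); dots are libraries in the order of replicates 1 to 3, and bars are mean ± SD. CRBN, IKZF1 and IKZF3 differ little between the groups, and in the other 9 genes the treated libraries lie outside the range of the DMSO libraries.

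Several genes of the amino acid response and of the antioxidant response rose. Of 38 tested genes of the list for ATF4, the transcription factor of amino acid shortage, 7 were called higher and 0 lower (17 higher and 1 lower adjusted over the list alone). ASNS was at a log2 change of 0.98 (95% interval 0.74 to 1.22), and PHGDH at 53.6 ± 6.3 against 106.6 ± 24.2 CPM. ALDH1L2, a mitochondrial folate enzyme, was 1.83-fold higher. Of 27 tested NRF2 targets, 6 were called higher and 0 lower (16 higher and 0 lower adjusted over the list alone). They included AKR1C1 (57.2 ± 1.0 to 103.7 ± 15.2 CPM), the quinone reductase NQO1 (72.4 ± 1.5 to 115.5 ± 13.5 CPM), PIR and ME1. Of 33 proteasome subunits 31 had a positive fitted change, and edgeR called 1, PSMC2 (234.9 ± 5.65 to 291 ± 18.2 CPM), with 15 higher adjusted over the list alone. DESeq2 called 15 ATF4 genes higher and 1 lower, 12 NRF2 targets higher and 7 proteasome subunits higher. In the same order, edgeR with GC and length offsets called 19 higher and 1 lower, 14 higher and 12 higher. All 3 lists were called upward by camera, with adjusted p values of 1.30e-05 for the ATF4 list, 4.57e-07 for the NRF2 targets and 1.19e-07 for the proteasome. These calls were lost with an estimated correlation (adjusted p = 0.562, adjusted p = 0.428 and adjusted p = 0.364 with an estimated correlation). The median log2 change of the members was 0.21, 0.25 and 0.15, and after GC and length offsets 0.23, 0.26 and 0.13. Rifamycin O replicate 3 moved less than the other treated libraries. The mean log2 deviation of the ATF4 list from the DMSO mean was 0.40, 0.28 and 0.12 in rifamycin O replicates 1 to 3, against 0.07 in the highest DMSO library. For NRF2 targets it was 0.39, 0.39 and 0.17, and for the proteasome 0.16, 0.18 and 0.11. By fry the ATF4 list was not called (adjusted p = 0.145). Of the 7 called ATF4 genes, 2 were called without rifamycin O replicate 2 and 5 without rifamycin O replicate 1. Of the 6 NRF2 targets, 5 were called without either of these libraries or DMSO replicate 1. PSMC2 was called only without DMSO replicate 3 or rifamycin O replicate 3. With GC and length offsets, the 7 ATF4 genes and 6 NRF2 targets stayed called when each library was left out in turn. PSMC2 again was called only without DMSO replicate 3 or rifamycin O replicate 3.

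Several erythroid genes rose as well. Of 27 tested erythroid markers, 8 were called higher and 0 lower (17 higher and 1 lower adjusted over the list alone). They included the glycophorins GYPB (1.56-fold) and GYPE (1.45-fold), and carbonic anhydrase CA1 (1.66-fold). Of 9 tested globins, 4 were called higher and 0 lower (7 higher adjusted over the list alone). These were the fetal globins HBG2 (2787 ± 144 to 3641 ± 38 CPM) and HBG1 (1893 ± 111 to 2369 ± 41 CPM) and the embryonic HBE1 (1.26-fold) and HBZ (1.36-fold). Of 14 genes of heme synthesis and transport, ABCB10 (1.28-fold) and ALAS2 (1.31-fold), the first enzyme of the pathway in red cells, were called higher, and 8 were higher adjusted over the list alone. Of 22 tested genes of iron handling, the mitochondrial iron importer SLC25A37 (1.27-fold), the ferritin gene FTH1 (1652 ± 124 to 2153 ± 151 CPM) and BLVRA (49.7 ± 1.19 to 62.1 ± 1.00 CPM) were called higher, and 6 were higher adjusted over the list alone. DESeq2 called 15 erythroid markers, 6 globins, 6 heme genes and 6 iron genes higher, and edgeR with GC and length offsets 19, 6, 8 and 7. Limma-voom called 5, 3, 0 and 3. Camera called all 4 lists upward, with adjusted p = 2.58e-08 for erythroid markers, 1.05e-04 for globins, 5.00e-05 for heme synthesis and 0.0278 for iron handling. With an estimated correlation none was called: adjusted p = 0.428 with an estimated correlation for erythroid markers, and adjusted p = 0.364 with an estimated correlation for each of the other 3. The medians were 0.26, 0.31, 0.23 and 0.08 on the log2 scale, and 0.29, 0.29, 0.22 and 0.05 after GC and length offsets. The mean log2 deviation of erythroid markers was 0.37, 0.31 and 0.17 in rifamycin O replicates 1 to 3. Of the 8 called erythroid markers, 0 were called without rifamycin O replicate 2, 1 without rifamycin O replicate 1, 2 without DMSO replicate 1 and 5 without DMSO replicate 2. Of the 4 globins, only HBG2 was called without rifamycin O replicate 1, rifamycin O replicate 2 or DMSO replicate 1. ABCB10 and ALAS2 were called only without DMSO replicate 3 or rifamycin O replicate 3. Of the 3 iron genes, 0 were called without DMSO replicate 1, rifamycin O replicate 1 or rifamycin O replicate 2. The iron list was no longer called without DMSO replicate 1 (adjusted p = 0.0971) or rifamycin O replicate 2 (adjusted p = 0.077). With GC and length offsets, the called members of these 4 lists all stayed called when each library was left out in turn. HBG1 and HBG2, HBA1 and HBA2, and GYPB and GYPE are near-identical copies that share reads, so the split of counts between the members of each group is uncertain.

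Megakaryocyte markers went both ways. Of 14 tested, edgeR called 1 higher and 1 lower. TUBB1, the tubulin of platelets, was called higher (1.68-fold) and ITGA2B lower. Adjusted over the list alone 4 were higher and 2 lower, DESeq2 called 4 higher and 1 lower, and GC and length offsets 3 higher and 2 lower. The list was not called (adjusted p = 0.767, camera), with a median of 0.04 and, after the offsets, 0.08. Neither gene was called without rifamycin O replicate 1 or without rifamycin O replicate 2, nor TUBB1 without DMSO replicate 1. Both stayed called without each library in turn when GC and length offsets were used.

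**Figure D3:**
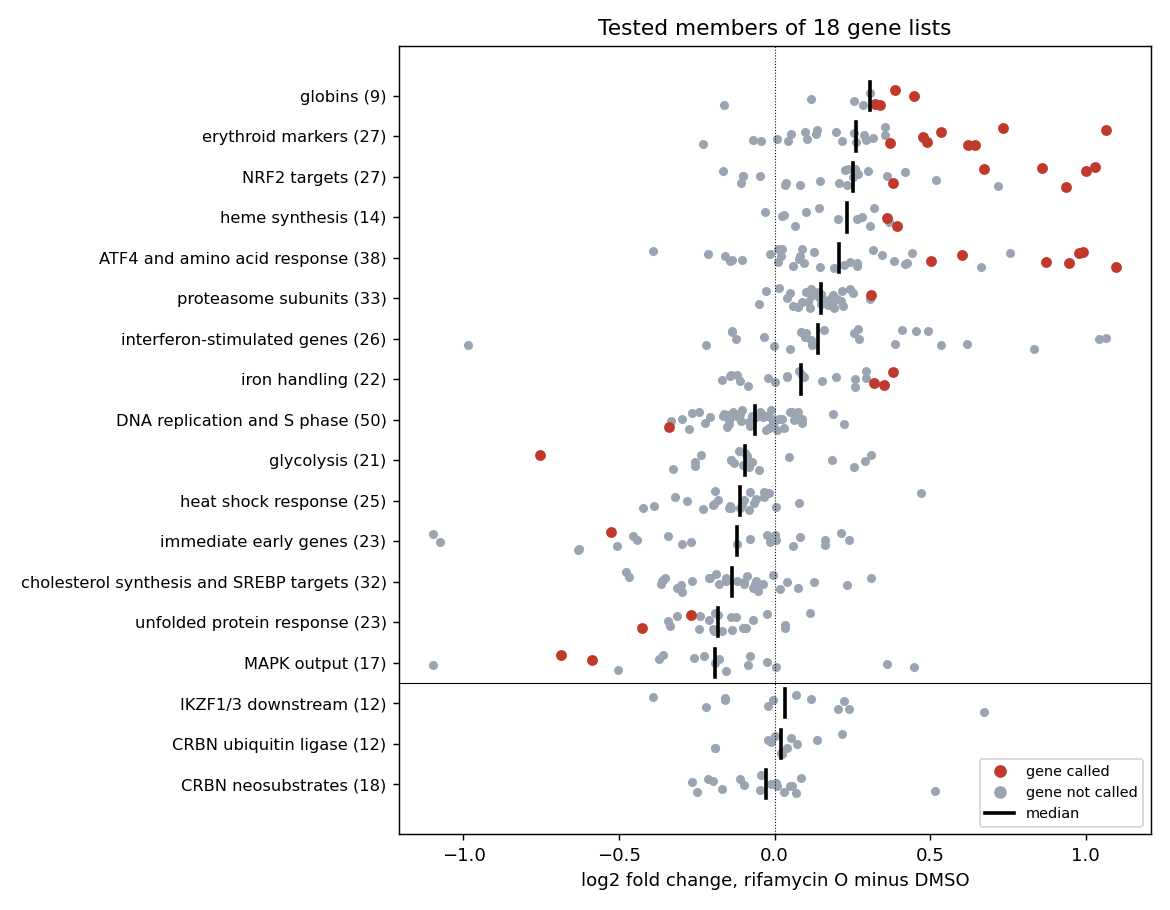
Fitted log2 fold change (horizontal axis) of each tested member of the 15 lists called by camera (above the line) and of 3 lists on CRBN and its substrates (below it), with the number of tested members in brackets; dots are genes, red where called, and black bars are medians. The medians run from −0.19 for MAPK output to 0.31 for globins, and 0 members of the 3 lists on CRBN are called.

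A pair of chaperone genes fell. Of 23 genes of the unfolded protein response, 20 had a negative fitted change and 2 were called lower. These were HSPA5, the main chaperone of the endoplasmic reticulum (525.6 ± 19.9 to 391.0 ± 28.1 CPM, 1.34-fold lower), and PDIA4 (1.20-fold lower). Adjusted over the list alone, 10 were lower. Of 25 tested heat shock genes, 22 had a negative fitted change and 0 were called by edgeR or limma-voom, with 11 at an unadjusted p below 0.05 by edgeR. Adjusted over the list alone 7 were lower, and DESeq2 called 3 lower. DESeq2 called 6 genes of the unfolded protein response lower. EdgeR with GC and length offsets called 11 genes of that list and 12 heat shock genes lower. HSPA1A was at 1164 ± 184 CPM in DMSO and 868 ± 50 CPM in rifamycin O. Camera called both lists downward, with adjusted p = 2.69e-05 and 5.74e-04, and neither with an estimated correlation (adjusted p = 0.364 with an estimated correlation for each). The medians were −0.18 and −0.11, and −0.19 and −0.13 after GC and length offsets. HSPA5 was not called without rifamycin O replicate 1 or without rifamycin O replicate 2, and PDIA4 was called only without DMSO replicate 3. Both stayed called without each library in turn when GC and length offsets were used.

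A few genes driven by MAP kinase signalling fell. Of 17 tested genes of MAPK output, SPRY4, a feedback inhibitor of the pathway (23.6 ± 1.2 to 14.6 ± 2.4 CPM), and MYEOV (68.3 ± 5.60 to 45.4 ± 7.66 CPM) were called lower. Adjusted over the list alone 5 were lower and 0 higher. Without either rifamycin O replicate 1 or rifamycin O replicate 2 neither was called, nor MYEOV without DMSO replicate 1. Of 23 tested immediate early genes, the AP-1 subunit JUND was called lower (1.44-fold lower), and 10 were lower adjusted over the list alone. JUND was not called without any one of the 3 rifamycin O libraries. SPRY4, MYEOV and JUND stayed called without each library in turn when GC and length offsets were used. DESeq2 called 4 genes of MAPK output and 6 immediate early genes lower, and edgeR with GC and length offsets 5 and 9. EGR1, a member of both lists, was at 238 ± 60 CPM in DMSO and 111 ± 51 CPM in rifamycin O, with an adjusted p of 0.061 by edgeR. Camera called both lists downward, with adjusted p = 0.00115 for MAPK output and 0.00921 for immediate early genes. The values were, in that order, adjusted p = 0.364 with an estimated correlation and adjusted p = 0.562 with an estimated correlation. The immediate early list was not called by fry (adjusted p = 0.241) or without DMSO replicate 3 (adjusted p = 0.0595). The medians were −0.19 and −0.12, and −0.20 and −0.08 after GC and length offsets.

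A further 4 lists were called by camera with few or 0 called members. The list of cholesterol synthesis and SREBP targets was called downward (adjusted p = 0.00287). The call was lost with an estimated correlation (adjusted p = 0.594 with an estimated correlation) and by fry (adjusted p = 0.25). Of its 32 tested members edgeR called 0, with 14 at an unadjusted p below 0.05, 8 lower and 2 higher adjusted over the list alone, and DESeq2 called 6 lower. EdgeR with GC and length offsets called 8 lower and 2 higher. The list's mean log2 deviation from the DMSO mean was −0.19 and −0.23 in rifamycin O replicates 1 and 2. In rifamycin O replicate 3 it was −0.01, inside the range of the DMSO libraries, and 0.02 after GC and length offsets, above all 3 DMSO libraries. The S phase list was called downward (adjusted p = 0.0138), but not with an estimated correlation (adjusted p = 0.364 with an estimated correlation). Of 50 members edgeR called 1, UHRF1 (log2 change −0.34), and 4 were lower adjusted over the list alone. DESeq2 called 4 lower, limma-voom 0, and edgeR with GC and length offsets 8 lower. Of the 6 libraries, only leaving out DMSO replicate 3 kept the call of UHRF1. The S phase call was lost without DMSO replicate 2 (adjusted p = 0.0547), rifamycin O replicate 1 (0.0573) or rifamycin O replicate 3 (0.0753). The glycolysis list was called downward (adjusted p = 0.0334), but not with an estimated correlation (adjusted p = 0.645 with an estimated correlation) or by fry (adjusted p = 0.263). Of 21 members edgeR called 1, SLC2A3, and 3 were higher and 6 lower adjusted over the list alone. DESeq2 called 1 higher and 3 lower, and edgeR with GC and length offsets 3 higher and 7 lower. SLC2A3 was not called without rifamycin O replicate 1 or without rifamycin O replicate 2. UHRF1 and SLC2A3 stayed called without each library in turn when GC and length offsets were used. The glycolysis call was also lost with GC and length offsets (adjusted p = 0.0983), without DMSO replicate 3 (0.186), without rifamycin O replicate 2 (0.077) and without rifamycin O replicate 3 (0.11). The interferon list was called upward (adjusted p = 0.00867), but not with an estimated correlation (adjusted p = 0.364 with an estimated correlation) or by fry (adjusted p = 0.0639). Of its 26 members edgeR called 0, with 5 at an unadjusted p below 0.05 and 1 higher adjusted over the list alone, and DESeq2 called 1 higher. EdgeR with GC and length offsets called 2 higher. CMPK2 was at a log2 difference of 0.53 (adjusted p = 0.0679, edgeR). The interferon call was lost without DMSO replicate 2 (adjusted p = 0.069) or rifamycin O replicate 1 (0.0541). The medians of the 4 lists, in that order, were −0.14, −0.06, −0.09 and 0.14, and −0.11, −0.05, −0.05 and 0.19 after GC and length offsets. Over all lists the camera test needs care, since other groupings of the same 6 libraries, in which 0 genes were called, still called up to 12 lists. The grouping with 12 set DMSO replicates 1 and 2 and rifamycin O replicate 3 against the rest. Each other grouping holds DMSO and treated libraries on both sides and so can keep part of a treatment difference. Its list count is therefore no measure of false calls.

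The remaining 23 tested lists were not called. Targets of PXR, the nuclear receptor that rifamycins such as rifampicin activate in liver, had 8 tested members of 30, with 0 called by edgeR or DESeq2, 2 at an unadjusted p below 0.05 by edgeR, 2 higher with GC and length offsets and an adjusted p of 0.558 by camera. CYP3A4 had at most 1 read in any library, and the receptor gene NR1I2 at most 3, both named after their counts were seen. The p53 targets (adjusted p = 0.105), apoptosis regulators (0.412, though called downward by fry at an adjusted p of 0.0229), G2/M genes (0.508), cytosolic ribosomal proteins (0.558) and mitochondrially encoded mRNAs (0.285) were not called. The same held for MYC targets (0.058), lysosomal genes (0.058), hypoxia genes (0.175), metallothioneins and zinc genes (0.187), nuclear respiratory chain genes (0.277), STAT5 targets (0.277), DNA repair genes (0.42), mitochondrial ribosome genes (0.558), histones (0.558), NF-kB targets (0.855) and LXR targets (0.868). Of single members of uncalled lists, the lysosomal protease CTSL (1.32-fold), the mitophagy receptor BNIP3L (1.34-fold) and the transporter SLC30A10 (1.52-fold) were called higher, and none of these 3 was called without rifamycin O replicate 1 or without rifamycin O replicate 2, nor CTSL without DMSO replicate 1 and BNIP3L without DMSO replicate 2. These 3 genes stayed called without each library in turn when GC and length offsets were used. Markers of other cell types were low. Of 17 T and NK cell markers 4 were expressed enough to be tested, of 13 B and plasma cell markers 3, of 28 monocyte and granulocyte markers 10, and of 14 fibroblast and epithelial markers 6. None of these genes was called by edgeR, with 4 at an unadjusted p below 0.05, and DESeq2 called 1 fibroblast or epithelial marker higher. The monocyte and granulocyte list (adjusted p = 0.66) and the fibroblast and epithelial list (0.285) were not called by camera.

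The authors' deposited table of KEGG pathways tested a set of 348 genes against a background of 15002, and 26 of its 257 pathways had a p-value below 0.05 but 0 an adjusted p-value below 0.05. The smallest adjusted p-value in the authors' deposited table was 0.174, for pathogenic Escherichia coli infection, and the smallest p-value was 0.00152, for NF-kappa B signaling and for dilated cardiomyopathy. The deposited adjusted p-values do not follow the order of the p-values: both of the latter pathways have 0.393. The smallest adjusted p-value therefore does not mark the strongest pathway. That table names 199 different genes. Of these, 130 passed the filter on low counts used here, each with a fitted change of at least 1.5-fold, and 36 were called. The 69 others had a median of 2.67 reads per library.

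Several named genes overlap another tested gene in the annotation, and without strand their reads cannot be separated. ATF5 overlaps IL4I1 and NUP62 on the opposite strand, and their fitted log2 changes were 0.17 and −0.09. SLC6A9 overlaps an antisense gene without a symbol (ENSG00000230615), whose fitted log2 change was 1.00. PIR overlaps BMX, MS4A4A overlaps MS4A4E and MCAM overlaps CBL. AKR1C1 and AKR1C2 are close paralogs whose reads the counting may divide.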

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

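GC and length offsets, alone or with another choice, and the fit without both DMSO replicate 3 and rifamycin O replicate 2 were chosen after the data were seen. None of the 165 called genes changed sign where tested under any of the 24 alternative gene fits. The number called was 300 with upper-quartile scaling (27 at 2-fold or more), 1249 with no filter on low counts (136 at 2-fold or more, with 31495 genes tested), 743 with DESeq2 (302 higher and 441 lower), 14 with limma on log2(FPKM + 1) (10 at 2-fold or more) and 16 with limma on log2(FPKM + 0.1). Under each of the FPKM fits, 5 of the 164 called genes tested there were still called, as was 1 of the 24 genes taken by the rule for the largest changes. It was 1216 with GC and length offsets (37 at 2-fold or more) and 50 without DMSO replicate 3 and rifamycin O replicate 2. Without each library in turn it ran from 25 to 265, with 6 to 41 at 2-fold or more. With GC and length offsets and without each library, in the order DMSO replicates 1 to 3 and rifamycin O replicates 1 to 3, it was 500, 750, 610, 311, 307 and 1973; at 2-fold or more it was, in the same order, 24, 32, 31, 18, 21 and 95. The test against a fold of 2 (glmTreat) called 0 genes, with 24 at an unadjusted p below 0.05. The cause of these differences was not tested. Fewer libraries leave fewer degrees of freedom, yet leaving out 1 library did not always lower the count. From 165 it rose to 184 without DMSO replicate 2, 255 without DMSO replicate 3 and 265 without rifamycin O replicate 3. It fell without each of the others.

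With a replicate block the count was 357 (153 higher and 204 lower, 26 at 2-fold or more), and 1022 (29 at 2-fold or more) with GC and length offsets as well. The deviations of libraries with the same number correlated at −0.588, 0.417 and −0.02 for numbers 1 to 3. After GC and length offsets the values were −0.225, 0.122 and 0.004. They show no common sign. Deviations of 3 libraries centred within each group constrain one another, so this check cannot exclude that the numbers pair the samples. The block left 13 lists called, with iron handling and glycolysis at an adjusted p of 0.0543.

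The number of lists called was 15, and 12 to 20 under the alternatives except an estimated correlation, which called 0, with 3 at an unadjusted p below 0.05. Erythroid, globin, heme, NRF2, proteasome, unfolded protein, heat shock and MAPK lists were called in 25 of 26 alternatives each, with iron handling called in 20 and glycolysis in 11. None of the 15 lists turned direction. Fry called 12 lists, 10 of the 15 and the lists of CRBN neosubstrates and apoptosis regulators. Depth ran from 19334626 to 25036048 counts per library.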

Other observations

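The tests of explanations for the 3 patterns below, the split test of the number of called genes, the GC and length offsets and the KEGG pathways were chosen after the data were seen. The smallest p-values, outside the rule for named genes, included those of SRGN, the proteoglycan core protein serglycin (1.62-fold higher), and CD24, a surface glycoprotein (1.74-fold higher), each with an adjusted p of 0.00152 by edgeR. Of 297 KEGG pathways, camera called Proteasome (adjusted p = 4.85e-05) and Chemical carcinogenesis - DNA adducts (adjusted p = 0.00209), both higher. The second holds AKR1C2 and SULT1A1 among its 22 tested genes. Neither was called with an estimated correlation (adjusted p = 0.908 with an estimated correlation, with 4 pathways at an unadjusted p below 0.05), and fry called 0. With GC and length offsets camera called 5 pathways, these 2 and, lower, Spliceosome (adjusted p = 0.0104), Citrate cycle (0.0255) and Diabetic cardiomyopathy (0.03).

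With GC and length offsets, camera also called nuclear respiratory chain genes (adjusted p = 0.000609), cytosolic ribosomal proteins (0.0109), MYC targets (0.0126) and mitochondrial ribosome genes (0.0167) lower. It called lysosomal genes (0.00224) and fibroblast and epithelial markers (0.0473) higher. With an estimated correlation 0 lists were called after the offsets, with a smallest adjusted p of 0.132.

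Few genes were called among libraries that differ in GC trend. After GC and length offsets the common dispersion was 38.3% of the value without them on the same genes. It was 99.8% to 99.9% for 20 sets in which GC and length were shuffled together among genes. Shuffled values carry no trend to fit, so that outcome was nearly fixed in advance, and it does not separate GC from length. A trend with GC content or length that differs between libraries may account for part of the spread that limits the calls. What produced the trend was not tested.

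The lists of erythroid, globin and heme genes were called higher by camera, though not with an estimated correlation. GC or length bias as the whole cause is argued against by a mean log2 difference of 0.274 over 50 members after the offsets, against 0.256 before, with no overlap of the groups. Reads shared between near-identical copies are argued against by their sums, of which 4 of 4 were higher in every treated library. A shift away from megakaryocyte genes may contribute and stays open. The median of 14 such genes was 0.04, with ITGA2B lower and TUBB1 higher. Its standard error of 0.143 was taken over genes and does not measure the spread between libraries.

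The NRF2, ATF4 and proteasome lists were called higher and the chaperone lists lower by camera, and none with an estimated correlation (adjusted p from 0.364 to 0.562). After the offsets the mean log2 difference between the 2 sides was 0.378, against 0.377 before, which argues against GC or length bias as the whole cause. The summed AKR1C counts had a difference of group means of 0.871 on the log2 scale, with every treated library above every DMSO library, which argues against reads moved between copies. A general response to unfolded proteins would raise chaperones, and their mean was −0.138. That mean shows that the chaperone lists did not rise, but it restates part of the pattern and is no separate test of the explanation. No other biological explanation of this pattern or of the erythroid one was tested.

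The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. Every split but that of the treatment holds DMSO and treated libraries on both sides. A treatment difference then partly stays in the contrast and partly widens the spread within each side. The counts of the other splits are therefore no baseline for chance. The treatment split was the 1 split with the largest number of called genes, 165 against 0 in the highest other. It was also the 1 largest for genes at 2-fold or more (16 against 0), for called lists (15 against 12) and for genes called with GC and length offsets (1216 against 0). For KEGG pathways, 2 splits gave as many, with 2 for the treatment and 4 for the highest other.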
